A study of Mus musculus with 21 samples.

How the data were processed

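The study profiled RNA from mouse stomach corpus cells sorted by flow cytometry into 3 populations by the brightness of green fluorescent protein driven from the Lgr5 gene (Lgr5GFP high, low and negative). The mice had either been injected with tamoxifen, 0.27 mg per g of body weight, 24 hours before the cells were isolated, or left as controls. The control titles mark them as uninjected (Uninj), and no vehicle-injected group is among the samples. In comparisons of tamoxifen with control, the drug, the injection and the sorting run therefore cannot be told apart. Each tamoxifen population has 4 arrays and each control population 3, which gives 21 microarrays in 6 groups. Per the labels, total RNA was extracted with a micro column kit, amplified as cDNA, labelled with biotin and hybridised.

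The deposited table holds log2 signal made by the authors for each probe set (a set of probes for a transcript) on every array. Per the submitters' processing notes, R 3.2.3, limma 3.26.8, RMA and oligo were used, with no role or order given for each. The values run from 0.958 to 13.55 and the array medians from 3.95 to 4.25, the range that robust multi-array averaging gives. No genome build was given in the sources used here, so no positions are printed. The table has 41345 probe sets. Of these, 25335 are listed in the platform's gene table, 23521 with exactly 1 gene and 1814 with several, and 16010 are not listed. Gene symbols were updated by gene number for 23328 probe sets. Where a gene had more than 1 probe set (1082 genes), the 1 with the highest mean over the 21 arrays was used, which left 22180 genes for testing with no filter on level. As a guide to background signal, the 1105 olfactory receptor genes had a median log2 level of 2.54 and a 95th percentile of 4.25, and 12488 genes had a mean above that percentile. The number of arrays per group limits the precision of every value.

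Group means were fitted to the log2 values with limma 3.58.1 in R 4.3.3 (functions lmFit and eBayes, 15 residual degrees of freedom, 5.27 prior degrees of freedom). There were 12 comparisons. Tamoxifen was compared with control in each of the 3 populations, the 3 pairs of populations were compared within control mice and within tamoxifen mice, and 3 interaction terms tested whether the tamoxifen effect differed between populations. All tests were two-sided. A gene was called changed when its Benjamini-Hochberg adjusted p over all genes was under 0.05. Standard errors (SE) of differences come from this model, and standard deviations (SD) from the arrays of a group.

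The comparisons, the gene lists and the rule for naming genes were fixed before the data were examined. The 28 lists were cell type markers (chief cell, parietal cell, mucous neck cell, surface pit cell, endocrine cell, tuft cell, immune cell, fibroblast and smooth muscle, endothelial cell, erythroid cell, squamous epithelium, pancreatic acinar cell) and processes (S phase, G2 and M phase, Wnt target and stem cell, metaplasia and injury, immediate early and heat shock, unfolded protein response, p53 target, NRF2 target, cholesterol synthesis, interferon response, inflammatory response, EGFR ligand and MAPK feedback, Notch pathway, oxidative phosphorylation, ribosome biogenesis, lysosome and autophagy). Each list was tested against the remaining genes with camera from limma at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals. Members were counted as changed over all genes tested and adjusted over the list alone. The erythroid cell list had 1 measured member, which is too few to read as a list. Its log2 change with tamoxifen was -0.22 in high and -0.08 in negative cells, with camera adjusted p = 0.506 and 0.734, and in low cells the adjusted p was 0.558. The named genes were the 5 with the largest change each way among called genes whose groups did not overlap (the 3 largest each way for tamoxifen populations and interactions), up to 4 called members of each list with the smallest adjusted p, and a fixed panel of lineage, stem cell and injury genes. Predicted genes and genes of receptor families were left out of the first of these.

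Other settings were tried 1 at a time. They were cyclic loess normalization, the mean of a gene's probe sets, eBayes with trend and robust, array weights, a fit with only the groups compared, at least 2-fold change, leaving out the dimmest 25 percent of genes, the sorting run as a random block, the replicate or sorting run number as a fixed block, and leaving out each array in turn. For the lists, fry from limma was also run. After the data were seen, a replicate block, leave-one-out, the Wnt list without Lgr5 and fry with a random run block were added for lists. Treatment and sorting run are nested, since each run holds 1 treatment, so the run could enter a comparison between treatments only as a random block. Groupings of the same arrays other than the real one were also fitted. The fit was tested on simulated data with each gene's mean and 1 spread for all groups. Of 200 genes with a log2 change of 1, it recovered 62% for tamoxifen in high cells and 24.5% for the low minus negative interaction. With a change of 2 it recovered 97.5% and 88%. In these data, where genes vary independently, camera gave 1 of 100 random lists an unadjusted p under 0.05. Genes that vary together and groups of unequal spread, as here, were not simulated, so power and error rates there are not known.

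The design text describes the arrays as technical replicates from individual sorting runs, and the labels do not say how many mice they stand for. The p-values measure the spread between arrays, which may be technical. In the 3 control negative arrays 1 label names the population low while the title and the characteristics say negative. They were kept as negative, and their low Lgr5 signal is given with the results. No probe set values of the array table were left unused except those that name no single gene, which were fitted on their own. No pair of arrays had identical values.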

Results

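Mouse stomach corpus cells were sorted by Lgr5GFP brightness into high, low and negative populations, and gene expression was measured on microarrays in cells of tamoxifen-injected mice (n = 4 arrays per population) and of control mice (n = 3 arrays per population). The series title places the reporter in chief cells, the pepsinogen-secreting cells at the base of the gland, and names epithelial regeneration as its theme. A high dose of tamoxifen is known to injure the acid-secreting parietal cells of the mouse stomach. Lgr5 itself drives the reporter, so its difference between populations checks the labels and is no finding. Its mean log2 level was 8.79 (SD 0.38), 7.56 (SD 0.13) and 4.41 (SD 0.39) in control high, low and negative cells, and 8.43 (SD 0.29), 6.70 (SD 0.24) and 4.59 (SD 0.16) in the tamoxifen populations. Pearson correlations between arrays of a group ran from 0.944 to 0.991. Pgc, which encodes pepsinogen C, lay from 13.17 to 13.36 in the 6 groups, where the highest value of the table is 13.55, so its level on this array shows little about change. Some genes lay at or under a log2 level of 4.25, the 95th percentile of olfactory receptor genes, in the dimmer of the 2 groups. Their fold is given as a lower bound, at least the fold above that level. Unless stated, the 2 groups behind a named change between groups did not overlap on any array, and the named genes kept their call when any 1 array was left out.

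**Figure D1:**
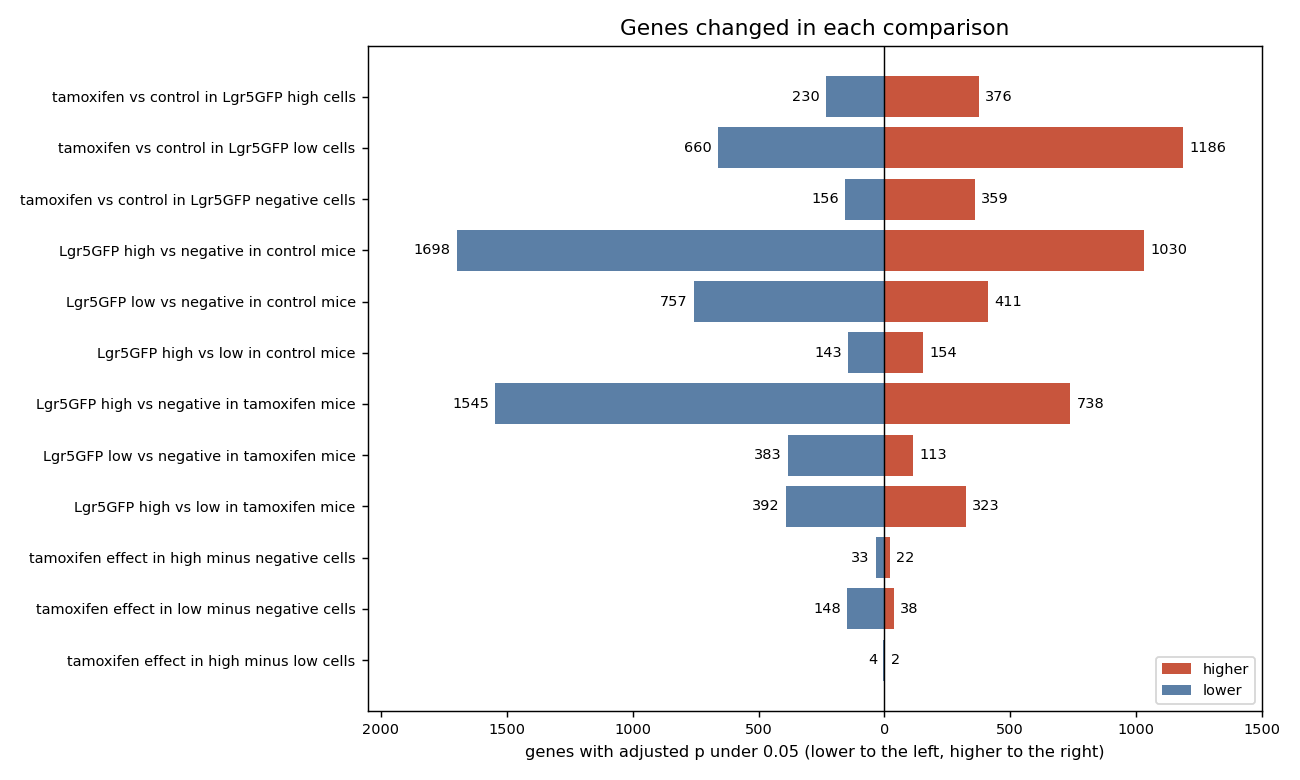
Number of genes called changed at an adjusted p under 0.05 in each of the 12 comparisons (limma, 22180 genes), lower to the left and higher to the right. Tamoxifen changed 1846 genes in Lgr5GFP low cells, 606 in high cells and 515 in negative cells.

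The comparison tamoxifen vs control in Lgr5GFP high cells asks what differed after tamoxifen injection in the cells with the brightest reporter. Dmbt1, a secreted glycoprotein of mucosal defence, rose 28.7-fold, from a mean log2 level of 5.19 (SD 0.88, n = 3) to 10.03 (SD 0.78, n = 4), a log2 change of 4.84 ± 0.49 (SE). Sprr1a, a precursor of the cornified envelope, rose at least 26.2-fold, from 4.24 (SD 0.06) to 8.96 (SD 0.67, adjusted p = 1.9e-07). S100a6, a calcium-binding protein, rose 17.3-fold, Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose 16.4-fold (log2 4.04, and 4.92 without tamoxifen high 4), and Mmp7, a secreted matrix metalloproteinase, rose at least 12.3-fold. Both subunits of the proton pump of parietal cells fell, Atp4b 10.8-fold (log2 -3.43, and -4.26 without tamoxifen high 3, adjusted p = 0.0069) and Atp4a 7.57-fold (adjusted p = 0.0013). Blm, a DNA helicase, fell 8.37-fold, and Sostdc1, a secreted modulator of BMP and Wnt signals, and Lpl, lipoprotein lipase, each fell 5.57-fold. The log2 change was 0.03 ± 0.12 for Pgc, -0.16 ± 0.17 for Cblif, which encodes intrinsic factor, and -0.06 ± 0.60 for the proliferation marker Mki67, with adjusted p = 0.94, 0.67 and 0.98, and the Mki67 change ran from -0.49 without control high 1 to 0.46 without control high 3.

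Among the lists in high cells, metaplasia and injury genes rose (median log2 1.08, and 0.61 without tamoxifen high 1, camera adjusted p = 6.12e-06, and adjusted p = 0.17 with an estimated correlation). Of 13 measured, 4 rose over all genes and 6 adjusted over the list alone, with Dmbt1, Cd14, a receptor for bacterial lipopolysaccharide (log2 2.36 ± 0.36), and Clu, a secreted chaperone (1.08 ± 0.14), among them. Immediate early and heat shock genes rose, 6 of 20 over all genes and 10 adjusted over the list alone, such as the cytokine feedback inhibitor Socs3 (adjusted p = 0.0067). Their median was 0.80 (adjusted p = 1.18e-07, and adjusted p = 0.17 with an estimated correlation). Ribosome biogenesis genes rose (median 0.59, adjusted p = 5.27e-09, and adjusted p = 0.25 with an estimated correlation), 4 of 19 and 12 on the list alone. Lysosome and autophagy genes rose (adjusted p = 0.00578, and adjusted p = 0.39 with an estimated correlation), 3 of 15 by either count, with the protease Ctsl at 1.32 ± 0.24 and the membrane protein Lamp2 at 1.02 ± 0.17. NRF2 targets rose (median 0.37, adjusted p = 0.011, and adjusted p = 0.37 with an estimated correlation), 1 of 12 and 5 on the list alone. Tuft cell genes fell (median -1.15, adjusted p = 1.71e-05, and adjusted p = 0.37 with an estimated correlation), 1 of 10 and 4 on the list alone. The size of that fall rests on tamoxifen high 1, with a tuft cell score of 7.09 against 8.69 to 9.79 in the other tamoxifen high arrays, and without it the median was -0.56 (adjusted p = 0.0041). Cholesterol synthesis genes fell, 2 of 17 over all genes, and adjusted over the list alone 7 fell and 1 rose. Their median was -0.41 (adjusted p = 2.25e-05, and adjusted p = 0.33 with an estimated correlation), and it was -0.26 without tamoxifen high 4, -0.17 without control high 1 and -0.70 without control high 2. Unfolded protein response genes fell, 2 of 20 over all genes, and on the list alone 6 fell and 1 rose, with Sdf2l1, part of a chaperone complex of the endoplasmic reticulum, at -1.48 ± 0.25. Their median was -0.31 (adjusted p = 0.00013, and adjusted p = 0.17 with an estimated correlation). Myc, a growth-promoting transcription factor of the Wnt target list, rose by 1.88 ± 0.30, while the Wnt list as a group had adjusted p = 0.84.

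Smaller list shifts in high cells each depended on single arrays. Chief cell genes had a median of -0.16 (-0.29 without control high 1, -0.26 without tamoxifen high 4), with 1 of 11 called (camera adjusted p = 0.0414, and adjusted p = 0.47 with an estimated correlation). That adjusted p was 0.19 without tamoxifen high 1, 0.37 without control high 2 and 0.16 without control high 3. Its changed member was Bhlha15, a transcription factor of secretory cells, at -1.64 ± 0.36 (adjusted p = 0.018, groups overlapping), whose call was lost without tamoxifen high 2, control high 3 or control high 2, with 0.078 the highest of these adjusted p. Parietal cell genes had a median of -0.17 (-0.06 without control high 1, -0.04 without tamoxifen high 2, -0.28 without control high 3, -0.26 without tamoxifen high 1 or control high 2), with 3 of 17 falling (adjusted p = 0.0413, and adjusted p = 0.54 with an estimated correlation). Camera gave 0.063 without tamoxifen high 2, 0.22 without tamoxifen high 4, 0.078 without control high 2 and 0.061 without control high 3. Interferon response genes had a median of 0.50 (0.90 without tamoxifen high 1, 0.80 without control high 2, 0.25 without control high 3), with 0 of 15 called by limma (adjusted p = 0.0123, and adjusted p = 0.60 with an estimated correlation). Without tamoxifen high 4 the adjusted p was 0.11, and without control high 3 it was 0.25. Inflammatory response genes had a median of 0.28, with 0 of 17 called by limma (adjusted p = 0.0413, and adjusted p = 0.37 with an estimated correlation). Without tamoxifen high 3 the adjusted p was 0.064, without tamoxifen high 4 it was 0.099 and without control high 3 it was 0.16. The other 16 lists did not pass, with camera adjusted p from 0.0537 for EGFR ligand and MAPK feedback to 0.878 for the Notch pathway, though camera called 6 of them without 1 array or another. In the mucous neck, immune, fibroblast, squamous and Wnt lists the median, the mean and the direction of camera differed in sign.

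Of 22180 genes, 376 rose and 230 fell in the comparison tamoxifen vs control in Lgr5GFP high cells (limma). Of all genes 10.4% had groups that did not overlap, where chance gives 5.71%. The count of 606 was 1702 without tamoxifen high 4, 335 without tamoxifen high 1, 338 without tamoxifen high 2, 215 without control high 1 and 236 without control high 2. With only these 7 arrays in the fit 12 genes passed, and of the genes named here Blm, Dmbt1, Mmp7, S100a6 and Sprr1a kept their call.

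The comparison tamoxifen vs control in Lgr5GFP low cells asks the same of the cells with a dimmer reporter. Sprr1a rose 53.4-fold, from 5.85 (SD 0.95, n = 3) to 11.59 (SD 0.23, n = 4). Hamp, the iron hormone hepcidin, rose at least 7.54-fold, from 2.20 (SD 0.20) to 7.16 (SD 0.90, adjusted p = 2.3e-07). Anxa3, a membrane-binding annexin, rose at least 23.5-fold, Tnip3, an inhibitor of NF-kB signalling, at least 15.6-fold, and Hspa1b, an inducible heat shock chaperone whose copy Hspa1a is nearly identical on the array, 17.5-fold. Bhlha15, known to maintain the secretory apparatus of chief cells, fell 8.08-fold (log2 -3.02 ± 0.36 SE, adjusted p = 3e-05), from 8.14 (SD 0.36) to 5.12 (SD 0.35). Falls of 12.7-fold to 15.9-fold were measured for Rgs13, Gnat3, Blm, Sostdc1 and Dclk1, of which Rgs13, Gnat3 (log2 -3.86, and -4.47 without tamoxifen low 3) and Dclk1 mark tuft cells. Lgr5, which drives the sorted reporter, differed by -0.86 ± 0.21 (adjusted p = 0.011), with 6.49 to 7.01 in tamoxifen and 7.48 to 7.71 in control low cells. Whether the low gate took the same range of cells under both treatments was not tested, which limits the other changes in low cells. Pgc (-0.03 ± 0.12), Cblif (-0.27 ± 0.17) and Mki67 (0.06 ± 0.60) were not called, with adjusted p = 0.93, 0.39 and 0.97. The Mki67 value near 0 rests on control low 3, at 8.12 against 5.18 and 5.79 in the other control low arrays. Without it the Mki67 change was 0.94 (adjusted p = 0.37), and without control low 1 it was -0.53 (adjusted p = 0.75).

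Among cell types in low cells, genes of the chemosensory tuft cells fell, 7 of 10 over all genes and 10 adjusted over the list alone. The median was -2.76 (camera adjusted p = 1.17e-11, and adjusted p = 0.067 with an estimated correlation). Parietal cell genes fell, 7 of 17 and 10 on the list alone, such as the potassium channel Kcnj16 (-2.01 ± 0.31), the water channel Aqp4 (-1.64 ± 0.26) and the anion exchanger Slc4a2 (-1.44 ± 0.24). Their median was -1.18 (adjusted p = 8e-08, and adjusted p = 0.067 with an estimated correlation). Atp4a (-1.45 ± 0.45, adjusted p = 0.050) and Atp4b (-1.94 ± 0.65, adjusted p = 0.073) were not called. Mucous neck cell genes fell, 2 of 7 and 4 on the list alone, with A4gnt, a glycosyltransferase of gland mucin, at -2.86 ± 0.61 and Agr2, a mucin-folding enzyme, at -1.94 ± 0.41. Their median was -1.41 (adjusted p = 0.000242, and adjusted p = 0.15 with an estimated correlation). Endocrine cell genes fell, 4 of 16 and 5 on the list alone, with the histamine-forming enzyme Hdc at -2.79 ± 0.42 and the vesicular monoamine transporter Slc18a2 at -2.44 ± 0.40 (-3.11 without control low 1). Their median was -0.79 (adjusted p = 4.81e-06, and adjusted p = 0.15 with an estimated correlation). Chief cell genes fell, 2 of 11 and 3 on the list alone, namely Bhlha15 and Copz2, a vesicle coat subunit (-1.47 ± 0.32). Their median was -0.37 (adjusted p = 0.000402, and adjusted p = 0.15 with an estimated correlation), and -0.21 without tamoxifen low 2. Surface pit cell genes as a group had adjusted p = 0.0691 (0.027 without control low 2), though Anxa10 (1.61 ± 0.28) and the mucin-like Mucl3 (2.15 ± 0.46) rose. Of the immune cell list, the lysosomal glycoprotein Cd68 rose at least 6.61-fold and the leukocyte gene Ptprc fell at least 5.33-fold, while the list had adjusted p = 0.317. For Ptprc, the overlap of the groups and the fits without 1 array are not given here. Endothelial genes had a median of -0.19, with 1 of 10 falling (adjusted p = 0.0261, and adjusted p = 0.15 with an estimated correlation). Camera no longer called them without tamoxifen low 1 (adjusted p = 0.056) or control low 3 (adjusted p = 0.072).

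Among processes in low cells, unfolded protein response genes fell, 11 of 20 over all genes and 16 adjusted over the list alone. Their median was -0.75 (camera adjusted p = 3.1e-12, and adjusted p = 0.0078 with an estimated correlation). The chaperones and folding enzymes Hyou1 (-1.53 ± 0.16), Sdf2l1 (-1.33 ± 0.25), Pdia6 (-1.25 ± 0.17) and Dnajc3 (-0.88 ± 0.13) were among them. Inflammatory response genes rose, 7 of 17 and 9 on the list alone, such as the chemokine Cxcl1 (at least 2.01-fold) and the NF-kB subunit Nfkb2 (1.63 ± 0.29). Their median was 0.59 (adjusted p = 8.95e-07, and adjusted p = 0.044 with an estimated correlation). Interferon response genes rose, 8 of 15 and 11 on the list alone, with the antiviral protein Rsad2 at least 5.91-fold higher and the immunoproteasome subunit Psmb8 at 1.81 ± 0.26. Their median was 1.75 (adjusted p = 1.77e-08, and adjusted p = 0.15 with an estimated correlation). NRF2 targets rose, 6 of 12 and 9 on the list alone, with heme oxygenase Hmox1 at 2.98 ± 0.52. Their median was 1.01 (adjusted p = 8.95e-07, and adjusted p = 0.067 with an estimated correlation). Immediate early and heat shock genes rose, 10 of 20 and 12 on the list alone. Their median was 0.69 (adjusted p = 3.2e-08, and adjusted p = 0.067 with an estimated correlation). Ribosome biogenesis genes rose, 12 of 19 and 13 on the list alone, with Nop58, a nucleolar protein, at 1.71 ± 0.29 and the helicase Ddx21 at 1.32 ± 0.25. Their median was 0.84 (adjusted p = 3.34e-12, and adjusted p = 0.067 with an estimated correlation). S phase genes rose, 7 of 19 and 10 on the list alone, with the replicative helicase subunit Mcm4 at 1.83 ± 0.37. Their median was 0.91 (adjusted p = 1.83e-06, and adjusted p = 0.18 with an estimated correlation). Of 19 G2 and M phase genes limma called 0, and the list had a median of 0.19 (adjusted p = 0.634). That rests on control low 3, with a list score of 7.02 against 4.52 and 5.09 in the other control low arrays and 5.43 to 6.10 in the tamoxifen low arrays. Without it the median was 0.94 (camera adjusted p = 0.00017), so whether these genes changed is not settled. Oxidative phosphorylation genes fell, 5 of 28 and 11 on the list alone, with Sdha at -0.89 ± 0.15 and Ndufs1 at -0.89 ± 0.18. Their median was -0.39 (adjusted p = 5.77e-09, and adjusted p = 0.067 with an estimated correlation).

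Further lists passed camera in low cells with smaller medians. Cholesterol synthesis genes fell, 3 of 17 by either count, with Insig1 at -1.41 ± 0.20 and Hmgcs1 at -1.37 ± 0.26. Their median was -0.45 (adjusted p = 0.000509, and adjusted p = 0.19 with an estimated correlation), and -0.30 without control low 3. Metaplasia and injury genes rose, 5 of 13 over all genes, and on the list alone 5 rose and 1 fell, with Cd14 at 3.66 ± 0.36, Dmbt1 at 3.19 ± 0.49 (2.55 without control low 1 and 3.99 without control low 3) and Clu at 1.22 ± 0.14. Their median was 0.59 (adjusted p = 0.00376, and adjusted p = 0.18 with an estimated correlation), and 0.13 without tamoxifen low 4. Wnt target and stem cell genes fell as a list, with 2 of 18 (1 of them Lgr5) falling and 1, Myc (1.58 ± 0.30), rising by either count. Their median was -0.41 (adjusted p = 0.00662, and adjusted p = 0.15 with an estimated correlation). Without Lgr5 the adjusted p was 0.0221, and adjusted p = 0.18 with an estimated correlation. p53 targets rose, 2 of 15 and 4 on the list alone, namely the death receptor Tnfrsf10b (1.39 ± 0.28) and Phlda3 (0.90 ± 0.20). Their median was 0.31 (adjusted p = 0.00376, and adjusted p = 0.15 with an estimated correlation), and 0.49 without control low 1. Lysosome and autophagy genes had a median of 0.30, with 3 of 15 rising (adjusted p = 0.0350, and adjusted p = 0.38 with an estimated correlation). Their call was lost without tamoxifen low 1 (adjusted p = 0.14) or control low 3 (adjusted p = 0.090). The fibroblast, squamous, acinar, EGFR and Notch lists did not pass, with adjusted p from 0.136 for acinar cells to 0.729 for Notch, and the median and mean of the squamous and Notch lists differed in sign.

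In all, 1186 genes rose and 660 fell in the comparison tamoxifen vs control in Lgr5GFP low cells (limma), 1846 together, and the groups of 21.2% of all genes did not overlap, against 5.71% by chance. The share that rose was 64.2% and became 50.7% after cyclic loess normalization. The count was 1226 without tamoxifen low 1, 990 without control low 1 and 1109 without control low 2.

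The comparison tamoxifen vs control in Lgr5GFP negative cells asks what changed in corpus cells without the reporter. Hamp rose at least 63.7-fold, from 2.35 (SD 0.32, n = 3), under the median of olfactory receptor genes (2.54), to 10.24 (SD 0.39, n = 4). Sprr1a rose 37.3-fold (log2 5.22 ± 0.35 SE, adjusted p = 2e-08), Pdk4 13.7-fold (log2 3.78, and 4.52 without tamoxifen negative 4), and Serpina7, which encodes thyroxine-binding globulin, at least 12.8-fold. Serping1, a complement inhibitor, rose at least 9.74-fold (at least 15.2-fold without tamoxifen negative 4, adjusted p = 0.0090, and 0.051 without control negative 1). A4gnt fell 13.0-fold (log2 -3.70 ± 0.61 SE, adjusted p = 0.0020). The mast cell protease Mcpt2 fell 9.76-fold, and the mast cell carboxypeptidase Cpa3 and the gasdermin Gsdmc2 each fell at least 2.84-fold. Mcpt2 and Gsdmc2 have near-identical relatives, so which copy the signal belongs to is uncertain.

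Endocrine cell genes rose in negative cells, 4 of 16 over all genes and 9 adjusted over the list alone. The median was 1.73 (camera adjusted p = 4.38e-10, and adjusted p = 0.13 with an estimated correlation). Scg5, a secretory granule protein, rose by 2.44 ± 0.35 (adjusted p = 0.00059), and Hdc by 2.13 ± 0.42 (adjusted p = 0.0076, and 0.058 without control negative 1), while Chga, the granule protein chromogranin A, differed by 2.17 ± 0.72 (adjusted p = 0.15). Parietal cell genes fell, 5 of 17 and 7 on the list alone, with the channel subunit Kcne2 at -2.04 ± 0.34 and Kcnj16 at -1.89 ± 0.31. Their median was -0.77 (adjusted p = 1.55e-08, and adjusted p = 0.11 with an estimated correlation). Mucous neck cell genes fell (median -1.58, and -0.97 without tamoxifen negative 4, 3 of 7 and 4 on the list alone, adjusted p = 8.77e-05, and adjusted p = 0.22 with an estimated correlation). Tuft cell genes fell too (median -0.97, 0 of 10 in limma and 2 on the list alone, adjusted p = 0.000861, and adjusted p = 0.36 with an estimated correlation). Immediate early and heat shock genes rose, 6 of 20 over all genes, on the list alone 7 rose and 1 fell, with Socs3 at 2.65 ± 0.36 and the small heat shock protein Hspb1 at 2.17 ± 0.37. Their median was 0.62 (adjusted p = 1.32e-08, and adjusted p = 0.11 with an estimated correlation), and 0.41 without tamoxifen negative 1. Inflammatory response genes rose (median 0.61, 1 of 17 and 8 on the list alone, adjusted p = 6.85e-06, and adjusted p = 0.11 with an estimated correlation). Interferon response genes rose (median 0.62, with 1.01 without control negative 2 and 0.32 without control negative 3, 1 of 15 by either count, adjusted p = 0.000341, and adjusted p = 0.36 with an estimated correlation), namely Psmb8 (adjusted p = 0.0027). The p53 targets rose (median 0.21, 1 of 15 and 3 on the list alone, adjusted p = 0.00324, and adjusted p = 0.21 with an estimated correlation), namely the cell cycle inhibitor Cdkn1a (2.11 ± 0.36). Metaplasia and injury genes rose, 3 of 13 over all genes, on the list alone 3 rose and 1 fell, with Cd14 at 2.68 ± 0.36 and Clu at 0.74 ± 0.14. Their median was 0.54 (adjusted p = 0.0038, and adjusted p = 0.35 with an estimated correlation). G2 and M phase genes fell (median -0.90, 0 of 19 in limma by either count, adjusted p = 7.62e-06, and adjusted p = 0.36 with an estimated correlation). This was no uniform shift, with list scores of 6.42, 5.995, 7.73 and 8.28 in tamoxifen negative 1 to 4 against 7.79 to 8.25 in the control negative arrays. Without tamoxifen negative 2 the median was -0.49 (adjusted p = 0.0065). Oxidative phosphorylation genes fell (median -0.28, 0 of 28 in limma, adjusted p = 9.8e-07, and adjusted p = 0.21 with an estimated correlation). Ribosome biogenesis genes rose (median 0.40, 0 of 19 in limma, adjusted p = 8.14e-05, and adjusted p = 0.36 with an estimated correlation).

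Other list calls in negative cells were lost without single arrays, and each had adjusted p = 0.36 with an estimated correlation. For lysosome and autophagy (median 0.31, and 0.18 without tamoxifen negative 1, camera adjusted p = 0.0184, 1 of 15 rose, namely Ctsl at 1.53 ± 0.24) they were tamoxifen negative 1 (adjusted p = 0.073), tamoxifen negative 2 (0.061) and control negative 2 (0.065). For immune cells (median 0.30, with 0.54 without tamoxifen negative 1, 0.12 without tamoxifen negative 3 and 0.15 without control negative 2, adjusted p = 0.0409, 2 of 17 rose and 1, Cpa3, fell) they were tamoxifen negative 3 (0.32), tamoxifen negative 4 (0.092) and control negative 2 (0.15), and Cd68 rose by 2.14 ± 0.24. For fibroblast and smooth muscle (median -0.23, and -0.15 without tamoxifen negative 1, adjusted p = 0.0166, 0 of 13 in limma) they were tamoxifen negative 1 (0.061), tamoxifen negative 3 (0.070) and control negative 2 (0.065). For cholesterol synthesis (median -0.30, and -0.16 without tamoxifen negative 4, adjusted p = 0.0102, 0 of 17 and 1 on the list alone) it was tamoxifen negative 4 (0.20). For the unfolded protein response (median -0.11, with -0.18 without tamoxifen negative 3, -0.17 without control negative 2 and -0.06 without tamoxifen negative 4, adjusted p = 0.0383, 0 of 20 and 2 on the list alone) they were tamoxifen negative 4 (0.23), control negative 1 (0.060) and control negative 3 (0.079). Chief, pit, endothelial, squamous, acinar, S phase, Wnt, NRF2, EGFR and Notch lists did not pass, with adjusted p from 0.165 for NRF2 targets (0.04 without tamoxifen negative 2) to 0.920 for Wnt targets, and the acinar list's median and mean differed in sign.

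In the comparison tamoxifen vs control in Lgr5GFP negative cells 359 genes rose and 156 fell (limma), 515 together, and the groups of 15.3% of all genes did not overlap, against 5.71% by chance. The count was 883 without tamoxifen negative 4, 333, 248 and 251 without tamoxifen negative 1, 2 and 3, and 176, 229 and 206 without control negative 1, 2 and 3.

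Across the 3 populations, 50 genes rose with tamoxifen in each and 20 fell in each. Those that rose in each included Sprr1a (4.72, 5.74 and 5.22 in high, low and negative cells), Tnip3, Pdk4, Anxa3, Cd14, Clu and Socs3, and those that fell in each included Kcne2, the growth hormone receptor Ghr, the growth factor Igf1, the cysteine-forming enzyme Cth and catalase, Cat. Ghr, Igf1, Cth and Cat lay outside the rule for naming and were chosen after their values were seen. These shared sets were not tested by leaving out arrays. High and low cells shared 237 genes that rose and 111 that fell, low and negative cells 116 and 73, and high and negative cells 55 and 24. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.64 between high and low, 0.39 between high and negative and 0.43 between low and negative cells. In control mice the deviations of high and low arrays with the same title number correlated (r 0.22 to 0.32), and those of low and negative (0.11 to 0.23) and of high and negative arrays (0.09 to 0.17) did so less. Noise shared by the controls raises these overlaps and correlations, so neither was tested against chance. There were 16 genes that fell in low cells and rose in negative cells.

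**Figure D2:**
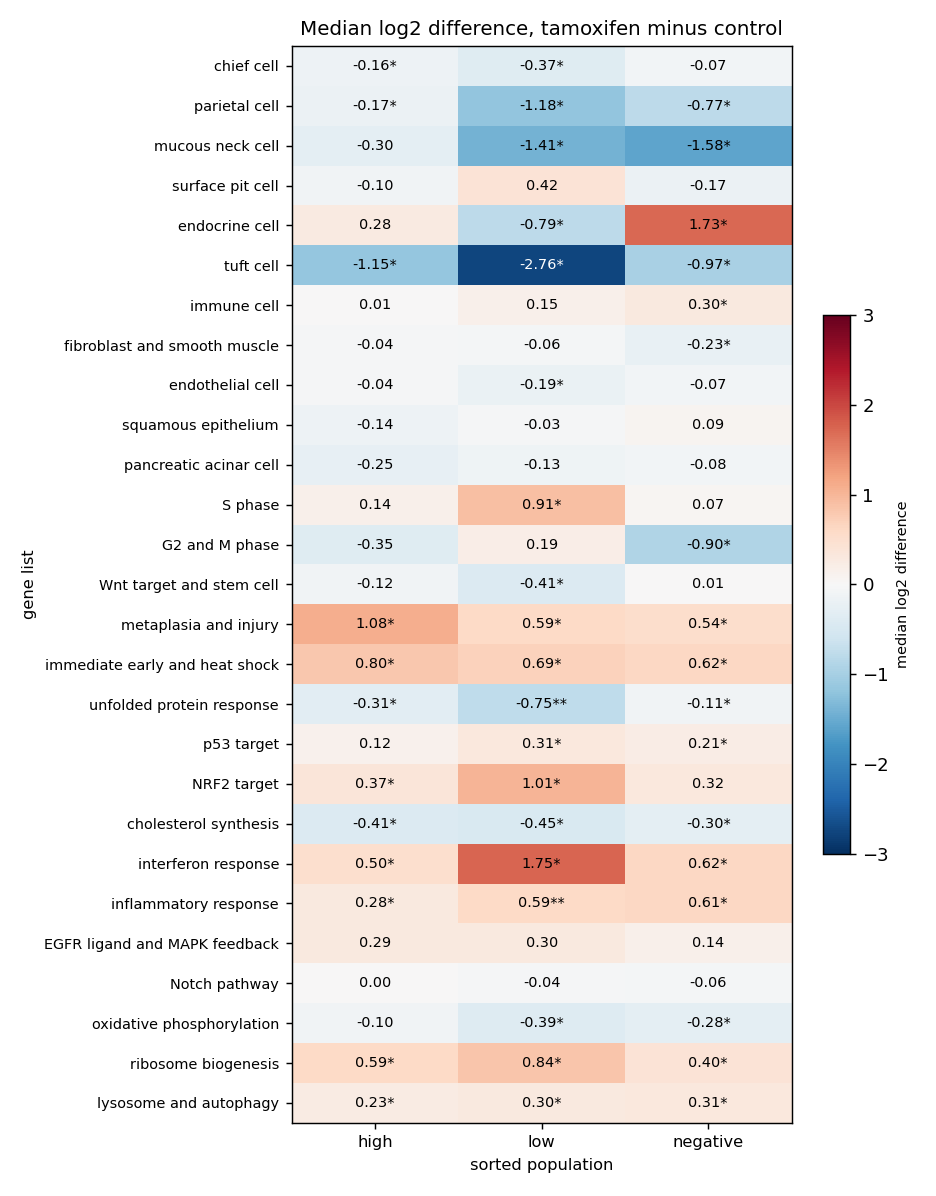
Median log2 change of each gene list except erythroid with tamoxifen in Lgr5GFP high, low and negative cells, from blue (lower) to red (higher). Here * marks a camera call and ** a call that also held with an estimated correlation. With tamoxifen, endocrine cell genes had a median of -0.79 in low and 1.73 in negative cells, and tuft cell genes of -2.76 in low cells.

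The interaction terms ask whether tamoxifen acted differently in the populations. Where a group lay at or under 4.25, the term is given with that level as the lowest and its adjusted p is from the values as measured. For the tamoxifen effect in low minus negative cells 186 genes passed, 38 higher and 148 lower (limma). Endocrine cell genes differed most, 5 of 16 lower over all genes and 11 adjusted over the list alone, with Hdc at -4.91 ± 0.59 (SE, adjusted p = 0.00021), Cpe, a prohormone-processing enzyme, at -4.43 ± 0.70 (-5.05 without tamoxifen low 4), Slc18a2 at -3.88 ± 0.57 (-4.55 without control low 1) and Scg5 at -3.07. The median was -2.88 (camera adjusted p = 8.76e-20, and adjusted p = 0.029 with an estimated correlation). Unfolded protein response genes were lower in the same term, 3 of 20 and 7 on the list alone, with Hyou1 at -1.44 ± 0.23. Their median was -0.58 (adjusted p = 2.11e-09, and adjusted p = 0.029 with an estimated correlation). The largest terms were Gprasp2 (-5.31, adjusted p = 0.0018) and Vtn, the matrix protein vitronectin (-5.05 ± 0.58, adjusted p = 0.00014), on the lower side, and Mcpt2 (3.29) and Anxa3 (2.94, adjusted p = 0.0010) on the higher side. Mcpt2 lay under 4.25 in low cells under both treatments, so a fall there could not be measured and its term shows only the fall in negative cells. The same holds for Gsdmc3, which also ended under that level in negative cells, so that no more than 0.996 of its term was measured. For Bhlha15 the term was -2.48 ± 0.51 (adjusted p = 0.023). That call was lost without tamoxifen low 1, control low 1, control negative 1, 2 or 3, or control low 2, where the adjusted p was highest at 0.078. For Lgr5, which drives the sorted reporter, the term was -1.05 ± 0.29 (adjusted p = 0.11), and for Chga it was -4.27 ± 1.02 (adjusted p = 0.051, and 0.017 without tamoxifen negative 4).

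For the tamoxifen effect in high minus negative cells 55 genes passed, 22 higher and 33 lower. Mmp7 was higher (log2 3.62, adjusted p = 4e-04), and Hamp (-5.998, adjusted p = 8.9e-07) and Serpina7 (-3.675, adjusted p = 5.2e-05) were lower. These terms take 4.25 as the lowest level, and Hamp and Serpina7 lay under it in high cells under both treatments, so theirs show only the rise in negative cells. Mcpt2 (3.29, adjusted p = 0.011) lost its call without control negative 2 (adjusted p = 0.062), and it lay under 4.25 in high cells under both treatments. Dmbt1 (3.77 ± 0.70, adjusted p = 0.023) lost its call without tamoxifen high 2, tamoxifen negative 2, control high 1 or 2, control negative 1 or 2, or control negative 3, where the adjusted p was highest at 0.081. Camera called 3 lists, the endocrine list as lower (adjusted p = 6.8e-07) and the mucous neck and parietal lists as higher (adjusted p = 0.00345 and 0.0288), and each had adjusted p = 0.66 with an estimated correlation. The mucous neck call was lost without tamoxifen high 1 (adjusted p = 0.092). The parietal call was lost without tamoxifen high 1 (0.10), tamoxifen high 3 (0.081), tamoxifen negative 2 (0.079), control negative 1 (0.081) or control negative 3 (0.057). For the tamoxifen effect in high minus low cells 6 genes passed, 2 higher and 4 lower, including Sycn, a secretory granule protein (1.24, adjusted p = 0.0044), Hamp (-2.915, adjusted p = 0.0044) and the adaptor Sdcbp2 (-2.28 ± 0.33, adjusted p = 0.0060). No list kept its call in this term with an estimated correlation.

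The count for tamoxifen effect in low minus negative cells was 386 without tamoxifen negative 4, from 98 to 116 without any other tamoxifen low or negative array except tamoxifen low 4, and from 71 to 86 without each control low or negative array except control low 3. The count for tamoxifen effect in high minus negative cells was 267 without tamoxifen negative 4, 132 without tamoxifen high 4, from 19 to 35 without tamoxifen high 2 or tamoxifen negative 1, 2 or 3, and from 9 to 25 without control high 1 or 2 or any control negative array. For tamoxifen effect in high minus low cells it was 3 without tamoxifen low 1 or control low 2 and 10 without tamoxifen low 4.

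**Figure D3:**
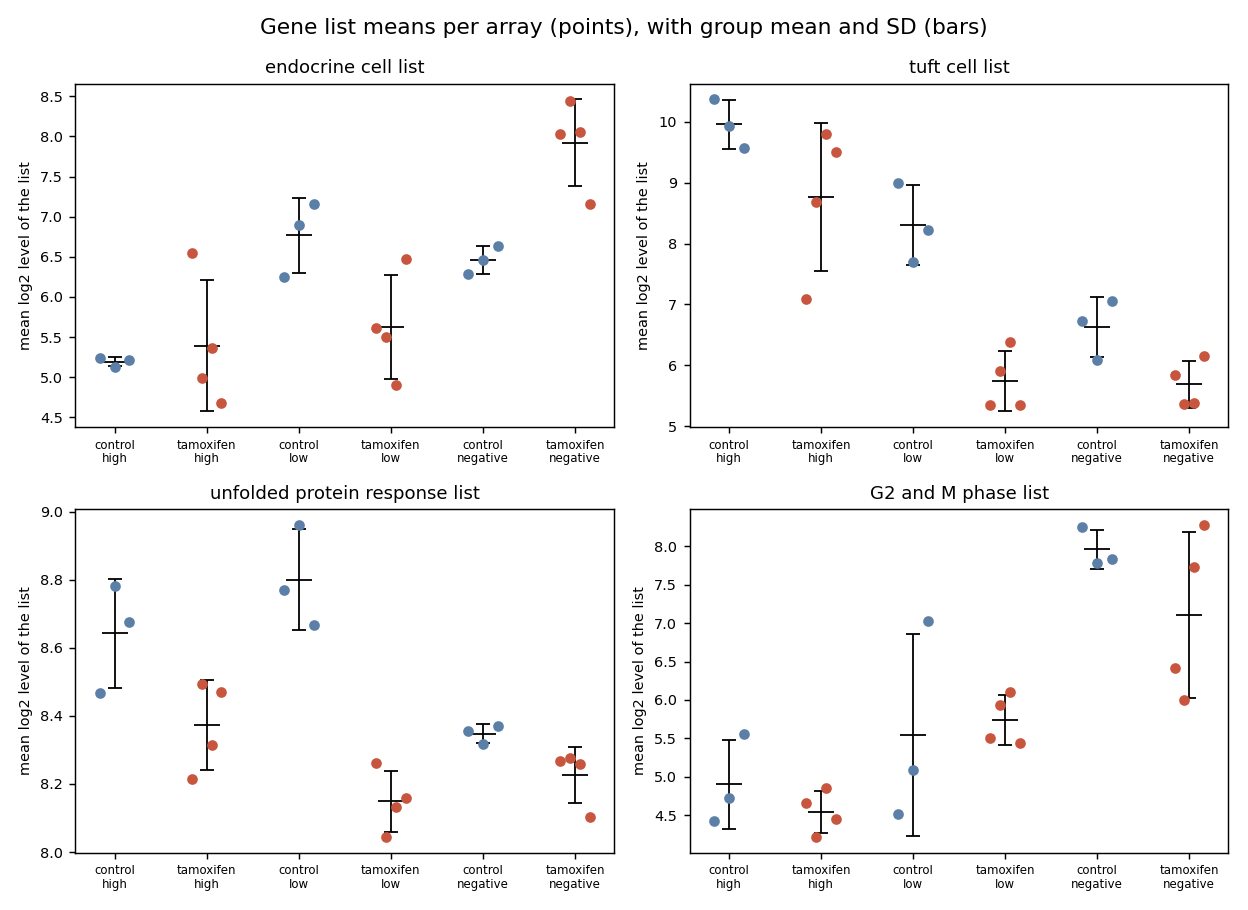
Mean log2 level of endocrine, tuft, unfolded protein response and G2 and M phase genes on each array, with group means and SD. The endocrine score was 6.77 in control and 5.62 in tamoxifen low cells, and 6.46 and 7.92 in negative cells.

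The comparison Lgr5GFP high vs negative in control mice asks what distinguishes reporter-bright cells from the rest of the corpus in uninjected mice. Mug1, a protease inhibitor, was at least 55.9-fold higher in high cells (10.05, SD 0.05, against 3.31, SD 0.57, n = 3 each), and the surface protein Cd177, the microvillar cadherin Cdhr5, the transcription factor Spib and Sh2d7 were 23.4-fold to 31.2-fold higher. The log2 difference of Cd177 was 4.96, and 4.07 without control high 1 and 5.61 without control high 3, and that of Spib was 4.66, and 3.93 without control negative 2. Chief cell genes were higher, with 5 of 11 higher and 1 lower by either count, such as Cblif (1.66 ± 0.18 SE) and Bhlha15 (2.28 ± 0.39). The median was 0.66 (camera adjusted p = 0.00115, and adjusted p = 0.22 with an estimated correlation), with 1.16 without control high 1, 0.24 without control high 2 and 0.35 without control negative 1. Wnt target and stem cell genes were higher, with 6 of 18 higher and 2 lower over all genes and 7 and 2 adjusted over the list alone, such as Nkd1 (at least 4.24-fold) and Ascl2 (at least 2.30-fold). Their median was 0.50 (adjusted p = 0.000116, and adjusted p = 0.064 with an estimated correlation). The list holds Lgr5, which the sort itself separates. Without it 5 of 17 were higher and 2 lower, with a median of 0.47 (adjusted p = 0.00288, and adjusted p = 0.14 with an estimated correlation). Axin2 was higher by 1.01 ± 0.24 and Myc was lower (-2.29 ± 0.32). All 10 measured tuft cell genes were higher by either count, with the tuft cell regulator Pou2f3 17.0-fold higher and Dclk1 at 3.91 ± 0.57. Their median was 3.45 (adjusted p = 4.56e-14, and adjusted p = 0.064 with an estimated correlation). The immune cell list was not called (adjusted p = 0.271). Of its 17 genes the leukocyte gene Ptprc was 17.5-fold higher, and 3 were lower, Cpa3 at least 2.84-fold, the lysozyme Lyz2 at least 3.10-fold and the signalling adaptor Tyrobp 2.73-fold. The call of Lyz2 was lost without control high 1 or control negative 1 or 3, and that of Tyrobp without control high 1 or 3 or control negative 1 or 3, with the highest adjusted p without control negative 1 (0.10 and 0.19).

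Among genes lower in control high cells, Mcpt2 was at least 16.8-fold, the membrane protein Emp1 60.6-fold and Muc5ac, the mucin of surface pit cells, 39.1-fold lower (log2 -5.29 ± 0.59 SE, adjusted p = 8.5e-06). Surface pit cell genes were lower, 9 of 12 lower and 1 higher over all genes, 10 and 2 adjusted over the list alone. Their median was -1.91 (camera adjusted p = 1.76e-09, and adjusted p = 0.015 with an estimated correlation). Cell cycle genes were lower, with all 19 measured G2 and M phase genes called (median -3.34, adjusted p = 3.15e-20, and adjusted p = 0.078 with an estimated correlation), including Cdk1 (-4.07 ± 0.63, and -3.37 without control high 1) and Mki67 (-3.73 ± 0.64), and 16 of 19 S phase genes, 19 on the list alone (median -1.80, adjusted p = 2.61e-17, and adjusted p = 0.064 with an estimated correlation). Oxidative phosphorylation genes were lower (median -0.68, 16 of 28 lower, on the list alone 21 lower and 1 higher, adjusted p = 1.35e-11, and adjusted p = 0.064 with an estimated correlation), as were ribosome biogenesis genes (median -0.91, 14 of 19 and 16 on the list alone, adjusted p = 1.35e-11, and adjusted p = 0.078 with an estimated correlation) and NRF2 targets (median -0.58, 5 of 12 by either count, adjusted p = 1.28e-05, and adjusted p = 0.078 with an estimated correlation), with Nqo1 at -4.08 ± 0.45. Parietal cell genes were lower (median -0.86, and -0.55 without control high 2, 5 of 17 lower and 1 higher, adjusted p = 0.0041, and adjusted p = 0.36 with an estimated correlation), and endocrine cell genes were lower (median -0.99, 6 of 16 lower and 1 higher, adjusted p = 0.00144, and adjusted p = 0.42 with an estimated correlation), with the hormone ghrelin, Ghrl, 16.1-fold lower. Of the genes tested, 1030 were higher and 1698 lower in Lgr5GFP high vs negative in control mice (limma), and the groups of 33.4% of all genes did not overlap, against 10% by chance.

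The comparison Lgr5GFP low vs negative in control mice asks the same of the dimmer population. Mug1 was at least 40.6-fold, the cytochrome P450 enzyme Cyp4v3 12.4-fold, Sostdc1 10.9-fold, Cdo1, which degrades cysteine, 9.83-fold and Reg3g, an antibacterial lectin with close relatives on the array, at least 8.90-fold higher in low cells. Chief cell genes were higher, 5 of 11 and 6 on the list alone, with Bhlha15 6.42-fold and Cblif 3.08-fold higher. The median was 1.56 (camera adjusted p = 6.97e-09, and adjusted p = 0.031 with an estimated correlation). Unfolded protein response genes were higher (median 0.42, 6 of 20 and 9 on the list alone, adjusted p = 1.44e-06, and adjusted p = 0.031 with an estimated correlation), including the secretory regulator Xbp1 (1.07 ± 0.19 SE). Wnt target and stem cell genes were higher (median 0.76, 6 of 18 higher and 1 lower over all genes, 9 and 1 adjusted over the list alone, adjusted p = 3.44e-06, and adjusted p = 0.031 with an estimated correlation), including Axin2 (1.21 ± 0.24). Without Lgr5, which the sort itself separates, 5 of 17 were higher and 1 lower, with a median of 0.68 (adjusted p = 0.000214, and adjusted p = 0.070 with an estimated correlation). Parietal cell genes were higher (median 0.56, 3 of 17 over all genes, on the list alone 8 higher and 1 lower, adjusted p = 1.45e-05, and adjusted p = 0.15 with an estimated correlation), such as the potassium channel Kcnq1 (2.28 ± 0.36), as were tuft cell genes (median 1.81, 3 of 10 and 8 on the list alone, adjusted p = 1.59e-07, and adjusted p = 0.16 with an estimated correlation).

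Mcpt2 was at least 16.8-fold, the retinol and alcohol dehydrogenase Adh7 at least 30.1-fold, Muc5ac 27.3-fold and Mucl3 23.6-fold lower in control low than negative cells. Surface pit cell genes were lower, 8 of 12 lower and 1 higher over all genes, 9 and 1 adjusted over the list alone. Their median was -1.32 (camera adjusted p = 1.53e-10, and adjusted p = 0.0080 with an estimated correlation). S phase genes were lower (median -1.37, 13 of 19 and 19 on the list alone, adjusted p = 1.46e-19, and adjusted p = 0.031 with an estimated correlation), with Mcm4 at -2.26 ± 0.40, and G2 and M phase genes were lower (median -2.62, 18 of 19 and 19 on the list alone, adjusted p = 2.95e-21, and adjusted p = 0.070 with an estimated correlation), with the checkpoint kinase Bub1 at least 6.34-fold lower. NRF2 targets were lower, 4 of 12 and 6 on the list alone, with Nqo1 at -4.04 ± 0.45 and Gsta3 at -3.94 ± 0.27. Their median was -0.64 (adjusted p = 2.3e-08, and adjusted p = 0.031 with an estimated correlation). In all, 411 genes were higher and 757 lower in Lgr5GFP low vs negative in control mice (limma), 1168 together, and the groups of 27.1% of all genes did not overlap, against 10% by chance. The count was 437 and 575 without control low 1 and 2, 558, 641 and 539 without control negative 1, 2 and 3, and 1807 with only these 6 arrays in the fit.

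The comparison Lgr5GFP high vs low in control mice asks what separates the brighter from the dimmer reporter cells. The lectin receptor Clec4a1 was at least 4.21-fold, the carboxypeptidase Cpvl 7.65-fold and Ptgs2, a prostaglandin-forming enzyme, at least 5.22-fold higher in high cells. Parietal cell genes were lower in high cells, 8 of 17 and 13 adjusted over the list alone, such as Kcnj16 (-2.46 ± 0.33 SE) and the nuclear receptor Esrrg (-2.26 ± 0.28). The median was -1.26 (camera adjusted p = 1.09e-19, and adjusted p = 0.0066 with an estimated correlation). Oxidative phosphorylation genes were lower, 8 of 28 and 23 on the list alone, such as Uqcrc1 (-1.01 ± 0.16), and the muscle-type cytochrome oxidase subunit Cox7a1 was 14.7-fold lower. Their median was -0.60 (adjusted p = 2.86e-26, and adjusted p = 0.0066 with an estimated correlation). Endocrine cell genes were lower (median -1.06, 5 of 16 lower, on the list alone 7 lower and 1 higher, adjusted p = 4.02e-09, and adjusted p = 0.20 with an estimated correlation), with Hdc 10.8-fold and Slc18a2 9.93-fold lower (log2 -3.31, and -3.98 without control low 1), and tuft cell genes were higher (median 1.64, 1 of 10 and 8 on the list alone, adjusted p = 1.16e-10, and adjusted p = 0.20 with an estimated correlation). Cblif (0.04 ± 0.18), Pgc (-0.05 ± 0.13) and Axin2 (-0.20 ± 0.24) were not called, with adjusted p = 0.99, 0.98 and 0.93. Chief cell genes as a list were lower (median -0.26, with -0.12 without control high 1 or 3, -0.11 without control low 2 and -0.42 without control low 3, 10 of 11 below 0, 0 called by limma, camera adjusted p = 0.0438, and adjusted p = 0.54 with an estimated correlation), a call lost without control high 1 (adjusted p = 0.49) or control low 2 (adjusted p = 0.19). In all, 154 genes were higher and 143 lower in Lgr5GFP high vs low in control mice (limma), 297 together, and the groups of 16.1% of all genes did not overlap, against 10% by chance. The count was 77 and 164 without control high 1 and 2, 94 without control low 2, and 147 with only these 6 arrays in the fit.

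**Figure D4:**
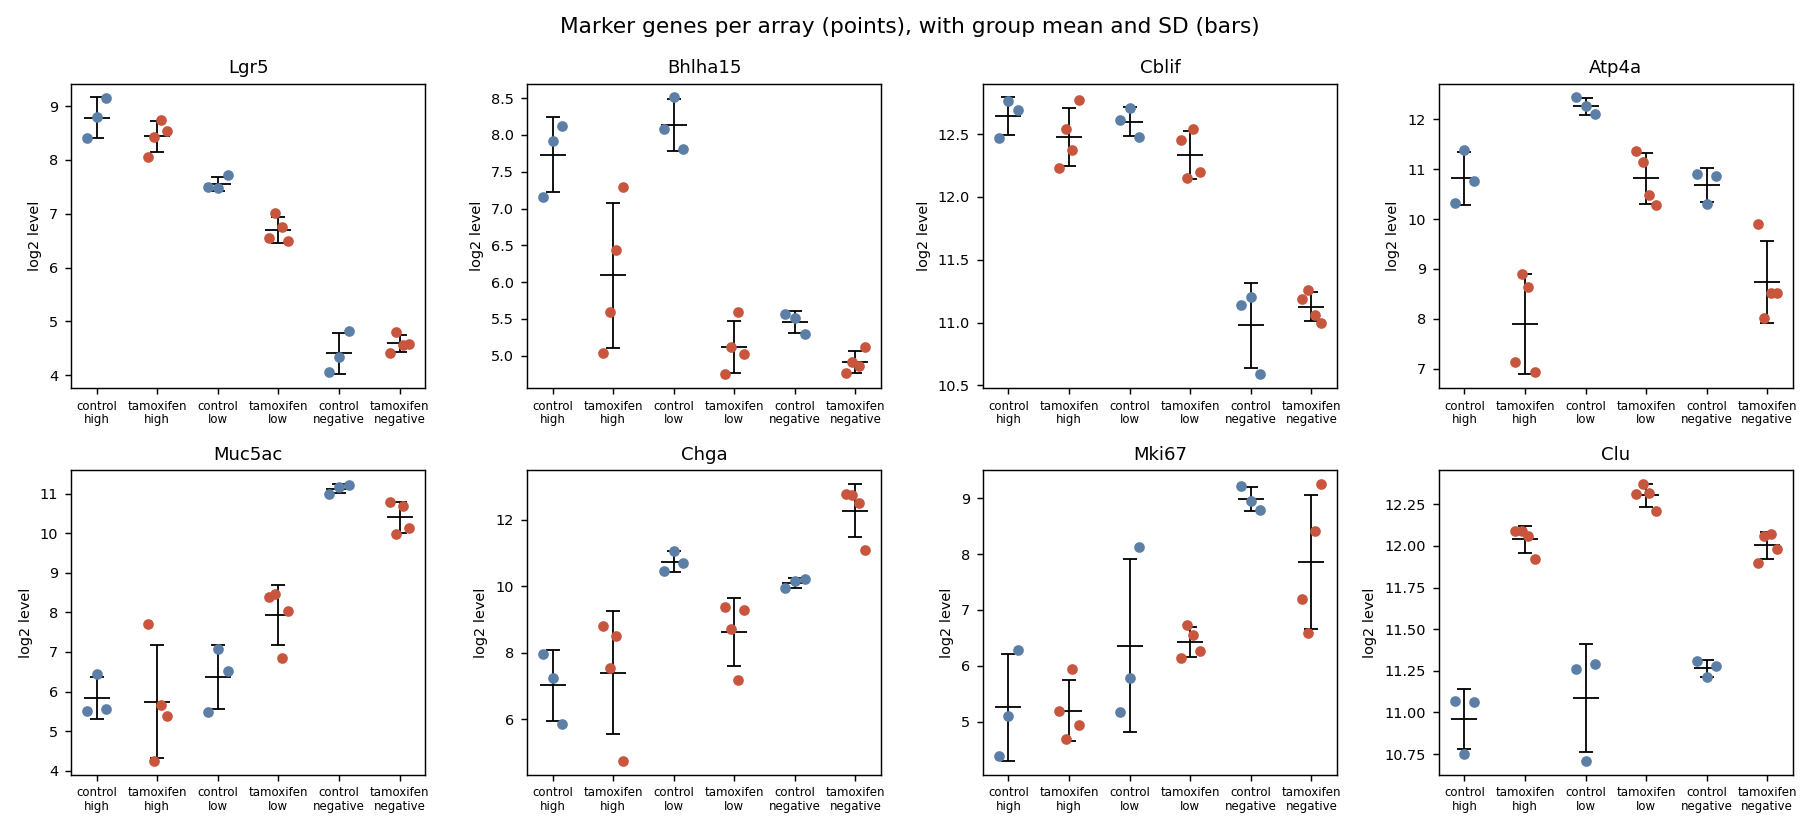
Log2 level of Lgr5, Bhlha15, Cblif, Atp4a, Muc5ac, Chga, Mki67 and Clu on each of the 21 arrays, with group means and SD. Bhlha15 lay at 7.73 in control high and 8.14 in control low cells and at 6.09 and 5.12 after tamoxifen, while Cblif lay between 12.33 and 12.64 in these 4 groups.

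Comparisons within tamoxifen mice ask which population differences were present after the injection. In Lgr5GFP high vs negative in tamoxifen mice, 738 genes were higher and 1545 lower (limma), 2283 together, and the groups of 10.9% of all genes did not overlap, against 2.86% by chance. Mug1 was at least 22.2-fold, Dclk1 22.0-fold and Spib 20.5-fold higher in high cells, and 9 of 10 tuft cell genes were higher, 10 adjusted over the list alone. The median was 3.58 (camera adjusted p = 3.83e-14, and adjusted p = 0.058 with an estimated correlation). Wnt target and stem cell genes were higher, 7 of 18 higher and 2 lower over all genes, 10 and 2 on the list alone, such as Sox9 (1.83 ± 0.26 SE). Their median was 0.63 (adjusted p = 1.44e-05, and adjusted p = 0.058 with an estimated correlation). Without Lgr5, which the sort itself separates, 6 of 17 were higher and 2 lower (adjusted p = 0.000562, and adjusted p = 0.079 with an estimated correlation). Hamp was at least 63.7-fold, Vtn 66.9-fold and Slc18a2 at least 50.7-fold lower in high cells. Endocrine cell genes were lower (median -2.65, 11 of 16 by either count, adjusted p = 6.2e-13, and adjusted p = 0.058 with an estimated correlation), as were surface pit cell genes (median -1.33, 10 of 12 lower over all genes, on the list alone 10 lower and 1 higher, adjusted p = 3.09e-12, and adjusted p = 0.0042 with an estimated correlation) and G2 and M phase genes (median -2.46, 19 of 19 by either count, adjusted p = 2.18e-19, and adjusted p = 0.078 with an estimated correlation). The count was 1428 without tamoxifen negative 3 and 938 with only these 8 arrays in the fit.

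In Lgr5GFP low vs negative in tamoxifen mice, 113 genes were higher and 383 lower (limma), 496 together, and the groups of 7.42% of all genes did not overlap, against 2.86% by chance. Mug1 was at least 18.4-fold and Thbs1, the matrix protein thrombospondin, 5.41-fold higher in low cells, and Atp4a was 4.22-fold higher. Rgs5 was 5.59-fold higher (adjusted p = 0.039), a call lost without any 1 of the 8 arrays, with the highest adjusted p of 0.12 without tamoxifen negative 1. Vtn was 37.6-fold, Serpina7 at least 12.8-fold and the lipase Cel 28.5-fold lower. Endocrine cell genes were lower, 10 of 16 and 12 adjusted over the list alone, with Hdc at -4.44 ± 0.39 (SE) and Chga at -3.63 ± 0.67. The median was -2.54 (camera adjusted p = 8.62e-23, and adjusted p = 0.018 with an estimated correlation). Surface pit cell genes were lower (median -0.81, 4 of 12 and 8 on the list alone, adjusted p = 7.43e-08, and adjusted p = 0.018 with an estimated correlation), whereas tuft cell genes did not differ detectably (median 0.11, 0 of 10 in limma, adjusted p = 0.974). The count was 315 and 295 without tamoxifen low 1 and 2 and 265 without tamoxifen negative 3.

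In Lgr5GFP high vs low in tamoxifen mice, 323 genes were higher and 392 lower (limma), 715 together, and the groups of 7.45% of all genes did not overlap, against 2.86% by chance. The share that was higher, 45.2%, became 64.4% after cyclic loess normalization. Dclk1 was 17.9-fold, Spib 17.7-fold and Hepacam2 17.5-fold higher in high cells, and 9 of 10 tuft cell genes were higher, 10 adjusted over the list alone. The median was 3.50 (camera adjusted p = 8.35e-21, and adjusted p = 0.034 with an estimated correlation). Atp4b was 20.6-fold (log2 -4.36, and -5.19 without tamoxifen high 3), Hamp at least 7.54-fold and the histone gene H2ac15 at least 4.64-fold lower, the last not called with array weights. Surface pit cell genes were lower (median -0.89, 5 of 12 and 8 on the list alone, adjusted p = 6.7e-07, and adjusted p = 0.034 with an estimated correlation), as were parietal cell genes (median -0.87, 6 of 17 lower, on the list alone 10 lower and 1 higher, adjusted p = 8.65e-07, and adjusted p = 0.11 with an estimated correlation). The count was 1118 without tamoxifen high 1, 365 and 437 without tamoxifen low 1 and 2, 245 with only these 8 arrays in the fit and 337 with array weights.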

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

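The count of endocrine genes that moved apart in low and negative cells, the changes of the other chief cell genes, Chia1 among them, and the score of tamoxifen high 4 on genes that rose elsewhere were tests chosen only after the results were seen.

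A test for 1 array far from the other 3 of its group was run on 160 sets of 4 tamoxifen arrays (panel genes, genes with the largest tamoxifen changes, and list scores) and found 10, and chance gives about 1 in 20 groups (5%). Levels are log2. In high cells, Atp4b was 8.59 in array 3 against 5.01 to 5.48 in the other arrays, Tff2 12.63 in array 1 against 11.50 to 11.64, and the interferon response list 4.63 in array 1 against 6.14 to 6.27. In low cells, the surface pit cell list was 8.65 in array 3 against 8.92 to 8.97. In negative cells, A4gnt was 4.56 in array 2 against 6.15 to 6.36 and the Wnt target and stem cell list 5.81 in array 1 against 5.59 to 5.61. Tamoxifen negative 4 stood apart for Chga (11.09 against 12.50 to 12.76), Gsdmc2 (3.81 against 2.21 to 2.39, all under 4.25, the 95th percentile of olfactory receptor genes, and so a difference within background), Pdk4 (6.48 against 9.37 to 9.48) and the unfolded protein response list (8.10 against 8.26 to 8.27).

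The tamoxifen effect differed between populations for 55 genes in high minus negative, 186 in low minus negative and 6 in high minus low cells, by the interaction term of limma. Of the panel genes and those with the largest tamoxifen changes, in high minus negative cells they were Blm (log2 -2.61), Dmbt1 (3.77), Gsdmc2 (3.08), Gsdmc3 (3.01), Hamp (-7.04), Mcpt2 (3.52), Mmp7 (3.51) and Serpina7 (-3.58). Leaving out 1 array ended the call of Dmbt1 (7 arrays, highest adjusted p = 0.081 without control negative 3) and of Mcpt2 (0.062 without control negative 2). In low minus negative cells they were Anxa3 (3.256), Bhlha15 (-2.48), Blm (-3.29), Gsdmc2 (3.19), Gsdmc3 (3.22), Hamp (-2.93), Mcpt2 (3.45), Mmp7 (2.04) and Serpina7 (-4.56), with the endocrine cell list (median -2.88) and the unfolded protein response list (median -0.58). Leaving out 1 array ended the call of Bhlha15 (6 arrays, highest adjusted p = 0.078 without control low 2), of Mmp7 (8 arrays, highest 0.077 without control negative 2) and of Hamp (0.052 without control negative 3). In high minus low cells the gene was Hamp (-4.11). Some of these genes lay under a log2 level of 4.25, the 95th percentile of olfactory receptor genes, in part of the groups, and differences under it were not measured. With that as the lowest level, the terms in high minus negative cells were 1.504 for Gsdmc2, 0.996 for Gsdmc3, -5.998 for Hamp, 3.29 for Mcpt2, 3.62 for Mmp7 and -3.675 for Serpina7. In low minus negative cells they were 2.94 for Anxa3, 1.504 for Gsdmc2, 0.996 for Gsdmc3, -3.08 for Hamp, 3.29 for Mcpt2, 1.89 for Mmp7 and -3.675 for Serpina7, and in high minus low cells -2.915 for Hamp. Gsdmc2, Gsdmc3, Mcpt2 and Serpina7 lay under it in high and low cells under both treatments, so their terms show only the change in negative cells, as does that of Hamp in high minus negative cells.

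Table entries that name no single gene (17824) lay outside the comparisons and were fitted on their own. With tamoxifen, 189 of them were called changed in high cells (130 higher, 59 lower), 283 in low cells (159 higher, 124 lower) and 67 in negative cells (41 higher, 26 lower).

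Endocrine cell genes fell in Lgr5GFP low cells and rose in negative cells with tamoxifen, with a median difference between these effects of -2.88. Cyclic loess normalization left that median at -2.88 and leaving out any 1 array left it at -2.51 or stronger, the weakest being without tamoxifen low 3, which argues against normalization and against 1 array as the cause. Of 16 measured genes, 15 were below 0 in low and above 0 in negative cells (Insm1 was the exception), as a different number of endocrine cells in each gate would give. The count uses the same values that showed the pattern, so it is no separate support for that explanation. A change of expression within endocrine cells was not tested, and both stay open.

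Bhlha15 and the unfolded protein response genes fell in Lgr5GFP low cells, where the median of the latter was -0.89 after cyclic loess normalization against -0.75 without it, which argues against normalization. Fewer chief cells in the gate would lower the other chief cell genes too, and 6 of them below a log2 level of 12 had a median of -1.05 (95% bootstrap interval -1.63 to -0.34) against -3.02 for Bhlha15, whose 95% limit nearest 0 was -2.26. Of these, the 4 bright enough to show such a fall had a median of -1.49 and an interval from -1.75 to -0.31. Both intervals are over a few genes of 1 list, which are not independent, so they only describe these genes. Pga5, among them, lay at 10.99 to 11.43 in control negative and 10.35 to 11.07 in control low cells, so it does not track chief cells here. The brighter Cblif and Chia1 changed by -0.27 and -0.10. They differed by only 1.62 and 1.68 between control low and negative cells, less than the Bhlha15 fall. They therefore cannot decide if fewer chief cells caused that fall. Fewer chief cells as all or part of the cause stay open, as does a lower Bhlha15 level per cell. For the unfolded protein response genes (-0.75 lies within the interval) fewer chief cells and lower levels per cell cannot be told apart.

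Tamoxifen high 4 lay nearest to the control high arrays, with a correlation of 0.975 to their mean against 0.949 to 0.961 for the other tamoxifen high arrays. On 116 genes that rose in low and negative cells its mean level was 6.68, between the control high arrays (5.91 to 5.97) and the other tamoxifen high arrays (7.06 to 7.26), which argues against a control array that carries a tamoxifen label. The low array of the same number scored 7.57 on 76 genes that rose in high (without array 4) and negative cells, within the 7.44 to 7.82 of the other tamoxifen low arrays, which argues against a weaker response of the run its title number gives. Its tuft cell score of 9.50 lay within the range of the other tamoxifen high arrays (7.09, 8.69 and 9.79), with 9.57 to 10.37 in the control high arrays. So wide a range cannot decide whether more tuft cells account for it. Its deviations went with those of low 3 (r = 0.34) and negative 4 (r = 0.32), which carry another number and score lowest of their groups on the 76 genes (7.44 and 6.85). A weaker run may therefore account for it if its title number is wrong. That and a weaker response in this 1 sample were not tested and stay open.

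For tamoxifen against control in high cells chance cannot be excluded from other splits of the arrays, since 2 of 35 splits gave as many changed genes (606 in the real split, 1924 in the highest other). That other split grouped tamoxifen high 4 with the 3 controls, which points to a structure of the samples. In low cells the real split alone gave as many (1 of 35, 1846 against 376). In negative cells chance cannot be excluded (2 of 35, 515 against 781, where tamoxifen negative 4 was grouped with controls). Within tamoxifen mice the real split alone gave as many for high against negative (1 of 35, 2283 against 230), low against negative (1 of 35, 496 against 59) and high against low (1 of 35, 715 against 72). A share of 1 of 35 is the lowest these splits can give, and they ignored the sorting run. They make chance less likely but do not exclude it. Within control mice 10 splits are too few for a share under 0.05, with 2728, 1168 and 297 genes in the real splits and 0 in the highest other of each (limma). For the interactions 100 splits were drawn. With the real one included, 3 splits gave as many changed genes for low minus negative (186 in the real split, 333 in the highest other). There were 7 for high minus negative (55 and 334) and 11 for high minus low (6 and 1748). Treatments were shuffled within each population, which breaks up the tamoxifen effect itself, and the sorting run was ignored. These splits therefore cannot decide whether chance explains an interaction.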

How the results depend on the processing

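The list test without Lgr5, and the replicate block, leave-one-out and fry with the sorting run as a random block in the list tests were chosen only after the results were seen. No called gene or list was called in the opposite direction, but the share of higher genes among those called crossed 50% with cyclic loess normalization for Lgr5GFP high vs low in tamoxifen mice (45.2% to 64.4%). The 12 counts of changed genes each stayed within 1.5 times under cyclic loess normalization, eBayes with trend and robust, the mean of a gene's probe sets and without the dimmest 25 percent of genes. Moved counts are given here for tamoxifen against control (T), control mice (C), tamoxifen mice (M) and the interactions (I). With only the groups compared they were 12 (T high), 1807 (C low against negative), 147 (C high against low), 938 (M high against negative), 245 (M high against low), 16 (I high minus negative) and 291 (I low minus negative). With array weights they were 1621 (T negative), 4810 (C high against negative), 2637 (C low against negative), 636 (C high against low), 337 (M high against low), 172 (I high minus negative) and 499 (I low minus negative). At 2-fold or more, a stricter threshold, they were 335 (T high), 926 (T low), 1700 and 739 (C high and low against negative), 1095 (M high against negative) and 368 (M high against low). The sorting run as a random block gave 84 (I high minus negative) and 13 (I high minus low), and the replicate block 1128 (T high) and 845 (T negative). Leaving out each array in turn moved 56 of 105 counts. The ranges were 215 (without control high 1) to 1702 (without tamoxifen high 4) for T high, 990 to 1715 for T low and 176 (without control negative 1) to 883 (without tamoxifen negative 4) for T negative. They were 1822 to 2564, 437 to 1276 and 77 to 421 for C high against negative, low against negative and high against low, and 1428 to 2657, 265 to 553 and 365 to 1118 for the same in M. They were 9 to 267, 71 to 386 and 3 to 10 for I high minus negative, low minus negative and high minus low. Except for the stricter threshold, the cause was not tested. Of 516 calls of named genes, 101 were lost with only the groups compared, 38 with array weights, 30 with the replicate block, 17 with cyclic loess, 17 with trend and robust, 4 with the mean of probe sets and 0 with the random block (limma), and leaving out 1 array lost 678 of 3796. Of 155 called list results, 137 lost their call with an estimated correlation and 18 kept it, and 67 lost it with fry, 8 with cyclic loess and 7 with array weights. Camera takes no random block, so that setting was run for the lists with fry alone, which lost 61. Without Lgr5 the Wnt list lost 1 call, in tamoxifen mice, low against negative (adjusted p = 0.0671). Signal over background limits the dim genes, since 12488 of 22180 genes had a mean above the 95th percentile of olfactory receptor genes.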

Other observations

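No explanation was tested in this part, and the genes that changed in each population (Ghr to Pigr) lay outside the rule for naming and were chosen after their values were seen.

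Cblif was higher in high and low than in negative cells under both treatments, by 1.66 and 1.62 in control and by 1.35 and 1.21 in tamoxifen mice. Mug1 lay at 10.05, 9.59 and 3.31 in control high, low and negative cells and at 8.72, 8.45 and 4.21 after tamoxifen, where 4.25 is the 95th percentile of olfactory receptor genes.

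Of the 20 genes that fell with tamoxifen in each population, Ghr, the growth hormone receptor, fell by 1.37, 1.89 and 0.87 in high, low and negative cells, and Igf1 by 1.32, 1.18 and 1.46. Pcca and Mmut, mitochondrial enzymes of propionate breakdown, fell by 0.74, 1.46 and 0.92 and by 0.82, 1.38 and 0.74, and Cat, catalase, by 0.70, 1.07 and 1.10. Among the 50 that rose in each, Osmr, a receptor subunit for oncostatin M, rose by 2.81, 2.77 and 1.67, and Pigr, the receptor that carries antibodies across epithelium, by 1.84, 1.41 and 1.60.

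In control mice the deviations of arrays with the same title number correlated between high and low cells (r 0.22 to 0.32) and between low and negative cells (0.11 to 0.23). In tamoxifen mice the highest correlations were 0.41 for low 3 with negative 4, which share a title number, and 0.34 for high 4 with low 3 and 0.32 for high 4 with negative 4, which do not. Array weights ran from 0.40 for tamoxifen high 4 to 3.45 for control negative 3. The consensus correlation within a sorting run was 0.075.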
